A study of Dugesia japonica with 19 samples.

How the data were processed

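The data come from m6A-REF-seq of the planarian Dugesia japonica, a freshwater flatworm that regrows missing body parts from pieces. The method uses MazF, an endoribonuclease that cuts RNA at ACA motifs when the adenosine is unmethylated and leaves the motif whole when it carries N6-methyladenosine (m6A). Per the labels, pieces of 10 to 20 planarians were pooled, total RNA was extracted, and messenger RNA was enriched by its poly(A) tail. There were 18 tissue libraries, 1 for each of head, trunk and tail on days 0, 1, 3, 5, 7 and 10. A single control library of intact animals was made by in vitro transcription (IVT), which copies the RNA without modifications.

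The deposited tables hold 1 tissue library each beside the control. Per the file headers, each row is a motif position and strand on an assembled transcript contig, with the count of uncut reads and the count of all reads, in the library and in the control. The control's count columns carry the letters fto beside IVT in the headers, and were taken as the IVT library. Each site has the same control counts in every table, as any single control library would give, so whether that library had a further treatment named by these letters is not settled, and the levels rest on this reading. The deposited fraction of uncut reads equalled uncut over all reads in every row, within a tolerance of 1e-09. The deposited m6A level, also a fraction, equalled the library's uncut share minus that of the control in all 23432 rows. FastQC, fastp 0.20.0 and HISAT2 2.4.2 are named in the submitters' processing notes, without their settings, and the counting program is not given in the sources used here. The deposited other value per row, the contig length in bases, was used for positions only.

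The filter behind the deposited lists was read from the values, since no source used here states it. No row had a level under 0.1, none had fewer than 11 uncut reads in both the library and the control, and the control's uncut share never passed 0.899. A library could therefore list a site on 1 read when the control had 11 uncut reads, and 59.9% of the rows were listed through control reads alone. A site absent from a list may have been unmethylated, unexpressed or too shallow, so it had no value rather than 0. Total sequencing depth was unknown, since only listed sites were counted. Reads at the 39 sites common to all 18 libraries stood in for relative depth within a tissue.

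Contig identifiers come from a transcript assembly, and the files do not pair them with gene names, so no gene is named. Gene lists fixed for neoblasts, axis patterning, the m6A machinery, neural, muscle, gut, epidermal, ribosomal, translation, chaperone, cytoskeletal and mitochondrial genes had no names to match and were not used here.

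Libraries were grouped by the tissue and day in the labels. With 1 library per tissue and day, the 6 days stood in for replicates in tissue comparisons, and the spread over days includes any change with time. Nothing in the labels says whether the tissues were prepared together, so a difference in preparation and a difference in tissue cannot be told apart. Pieces were pooled before extraction, so p-values measure the spread between libraries, not between animals. Tissue differences in the number of listed sites (log2) and in the median level were tested with exact two-sided sign-flip permutation tests over the 64 swaps within days, whose smallest p is 0.03125, with Benjamini-Hochberg adjustment over the 3 tissue pairs. Day 0 was set against later days by an exact two-sided test over the 216 placements of the day 0 label within tissues. Trends with day used Pearson's r and Spearman's rho with exact p-values over 720 orders. Overlap of lists was measured by the Jaccard index (shared sites over all sites in either list) and tested by 100000 two-sided permutations of tissue labels within days, or of day labels within tissues.

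Site levels were fitted with limma (lmFit and eBayes) with day as a block, over sites listed on at least 4 days in both tissues. Day 0 against later days used sites listed at day 0 in at least 2 tissues and in at least 6 later libraries, with tissue as a block. The Benjamini-Hochberg threshold for limma was 0.05 within each comparison. A difference of 0 within rounding was never called, a rule added after spurious calls were seen at sites with no residual spread when day 0 sites of any tissue were admitted. Fisher's exact test compared uncut and cut reads of each later day with day 0 within a tissue, site by site. That test compares pairs of libraries, not conditions, and reads of 1 library are not independent molecules. Confidence intervals of shares are Wilson intervals at 95% and cover counting error only.

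Sites named in the text followed a rule set before the data were examined. For each tissue pair, tested sites with the same sign on every shared day were ranked by mean difference, and for day 0 the largest coefficients with the same sign in every tissue were taken. Of each ranking of up to 10 sites, at most 2 in each direction are printed. The highest levels among sites in all 18 libraries and the contigs with the most sites completed the rule. Other choices set before the data were examined were the tests and most alternatives: minimum level, contigs in place of sites, plain numbers, mean levels, other sets of sites, coverage of 20 and 50 reads, each day left out, other overlap measures, logit levels, centring, no block, a variance trend and a quasi-binomial model. The relations between site numbers, depth and day, the turnover of lists and the correlation of uncut shares were also computed after the data were seen. Filters on control reads and on 10 reads, weights, uncorrected uncut shares and the removal of sites with identical levels were added after seeing the data.

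The site fits were checked on simulated reads drawn at the real coverage from 1 pooled uncut share per site. No spread between libraries beyond counting error was added, so recovery and false calls in the real data may differ. With 17 of 224 tested sites lowered by 0.2 in head against trunk, 41.2% were called and 0 unchanged sites were called. With a shift of 0.4, which pushed many sites off the simulated lists, 71.4% of the 7 that stayed were called. For head against tail a shift of 0.2 gave 29.4% of 17 changed among 153 tested sites, with 2 unchanged sites called (28.6% of its calls). For trunk against tail it gave 19.2% of 26 among 232, and for day 0 against later days 14.7% of 34 among 344. With a shift of 0.4, head against tail gave 66.7% of 6 among 138, with 1 unchanged site called. Trunk against tail gave 20% of 5 among 207 at that shift. The day 0 fit gave 66.7% of 12 among 323, with 1 unchanged site called. Without any shift the tissue fits called 0 sites and the day 0 fit called 1. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1, with figures by matplotlib 3.10.9.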

Results

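The level of m6A was measured base by base in head, trunk and tail pieces of regenerating planarians, to follow the modification along the body axis from day 0 to day 10. The 18 libraries listed 5847 distinct sites on 2882 contigs. Of these, 1700 sites were in 1 library only and 39 were in all 18. The sites lay on the minus strand of the contig in 56.4% of cases, and the median contig was 1701.5 bases long.

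The reads behind a site were few. Reads at listed sites came to between 12100 (head, day 10) and 834034 (trunk, day 5) per library. A site rested on 1 read in 24.7% of rows and on fewer than 10 in 58.0%. In 81.8% of rows no read was cut in the library, so that the level equalled 1 minus the control's uncut share. The control itself was far from fully cut, with a median uncut share of 0.706 over the listed sites and a share above 0.5 at 72.0% of them. The highest level a site could reach was set by that control share.

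Head libraries listed the most sites on average, but the difference between tissues was within the spread over days. Head listed 1839 ± 721 sites (SD, n = 6 days), trunk 950 ± 335 and tail 1117 ± 666. In head the numbers were 1790, 2749, 1695, 2374, 1796 and 631 on days 0, 1, 3, 5, 7 and 10. Trunk rose from 468 on day 0 to 1357 on day 10, and tail ranged from 447 on day 1 to 2375 on day 7. Head exceeded trunk by 0.91 on the log2 scale on average (higher on 5 of 6 days, exact sign-flip p = 0.156, adjusted p = 0.234). Head exceeded tail by 0.78 (4 of 6 days, exact p = 0.156, adjusted p = 0.234), and trunk minus tail was -0.13 (trunk higher on 4 of 6 days, exact p = 0.75). Day 0 lay 0.24 below the later days, at -0.24 (exact permutation p = 0.611). Within each tissue the number of sites followed the reads at the common sites, with Pearson r of 0.974 in head, 0.977 in trunk and 0.972 in tail (exact p = 0.0125, 0.00556 and 0.00556; adjusted p = 0.0433, 0.0333 and 0.0333 over 12 relations). Spearman's rho was 0.886, 0.829 and 0.829 (exact p = 0.0333, 0.0583 and 0.0583; adjusted p = 0.0667, 0.0875 and 0.0875), and without the 2 libraries farthest from the median r was 0.829, 0.872 and 0.851 but rho was 0.8, 0.4 and 0.4. In trunk the number of sites also rose with day (r = 0.899 and rho = 0.943, exact p = 0.0181 and 0.0167, adjusted p = 0.0433 for both, r = 0.863 without the 2 farthest days). That rise did not remain when reads were thinned at random to the depth of the shallowest trunk library (r = -0.412, exact p = 0.393). Thinning could only take sites off the later lists and left day 0 whole, so it cannot decide whether day had a share of its own. In head and tail r with day was -0.726 and 0.443 (exact p = 0.0861 and 0.372, adjusted p = 0.115 and 0.447), and without the 2 farthest days it was -0.529 and 0.983 over 4 days, so the tail value rests on those days.

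The median m6A level was lowest in head, intermediate in trunk and highest in tail on each of the 6 days. It averaged 0.218 ± 0.0107 (SD, n = 6 days) in head, 0.263 ± 0.0080 in trunk and 0.302 ± 0.0060 in tail. The share of listed sites with no cut read rose in the same order on average, but not on day 10, when it was 88.9% in head and 84.1% in trunk. It went from 76.0% ± 6.78 in head to 83.6% ± 0.93 in trunk and 93.8% ± 0.83 in tail, while the median reads per site, which limit the chance of seeing a cut read, were 11.3, 2.5 and 2.33. Levels of at least 0.5 were held by 13.8% ± 1.87 of head sites, 21.2% ± 1.09 of trunk sites and 27.5% ± 1.46 of tail sites. Head minus trunk was -0.0446, head minus tail -0.0841 and trunk minus tail -0.0395, each with the same sign on 6 of 6 days (exact sign-flip p = 0.03125 and adjusted p = 0.03125, the smallest the test can give). The control's share at the listed sites also differed, by 0.0415 between head and trunk, 0.0557 between head and tail and 0.0143 between trunk and tail (exact p = 0.03125 each). Part of the difference over all lists could thus lie in which sites were listed. The set of sites did not account for it alone. At sites listed in every library of both tissues (67 with trunk, 47 with tail), the head difference closest to 0 was still -0.0439. The mean level was 0.279 in head and 0.334 in trunk, while the mean uncut share was 0.949 and 0.955. Without subtracting the control, the mean uncut share of head minus trunk was -0.00542 (exact p = 0.156), and at sites with at least 50 reads trunk minus tail was -0.0156 (exact p = 0.5).

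**Figure D1:**
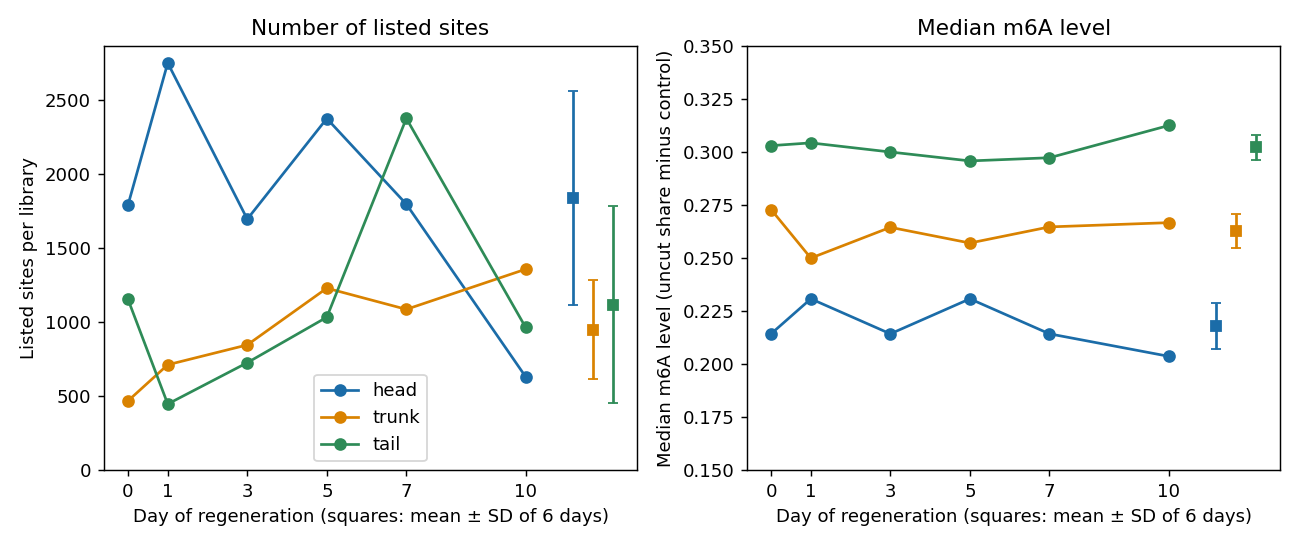
Number of listed sites per library (left) and median m6A level, a fraction (right), by day of regeneration, with 1 point per library and squares for the mean ± SD of the 6 days of head, trunk and tail. Site numbers cross between tissues, while the median levels keep the order 0.218 in head, 0.263 in trunk and 0.302 in tail on average.

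The lists of sites overlapped more within a tissue than between tissues. A list also depends on reads and expression, so this overlap is not one of methylation alone. The test of day used pairs of different tissues only and could not see a change with day within a tissue. Libraries of the same tissue on different days shared 0.361 of their sites by the Jaccard index, against 0.165 for libraries of different tissues and days. The difference of 0.196 had a permutation p of 0.00018, against a smallest possible share of relabellings of 0.000129. Libraries of different tissues on the same day shared 0.166, which differed from 0.165 by 0.00144 (permutation p = 0.795). Head libraries shared 0.399 with each other, trunk libraries 0.355 and tail libraries 0.329. Between tissues, trunk and tail shared 0.228, head and trunk 0.159 and head and tail 0.108.

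**Figure D2:**
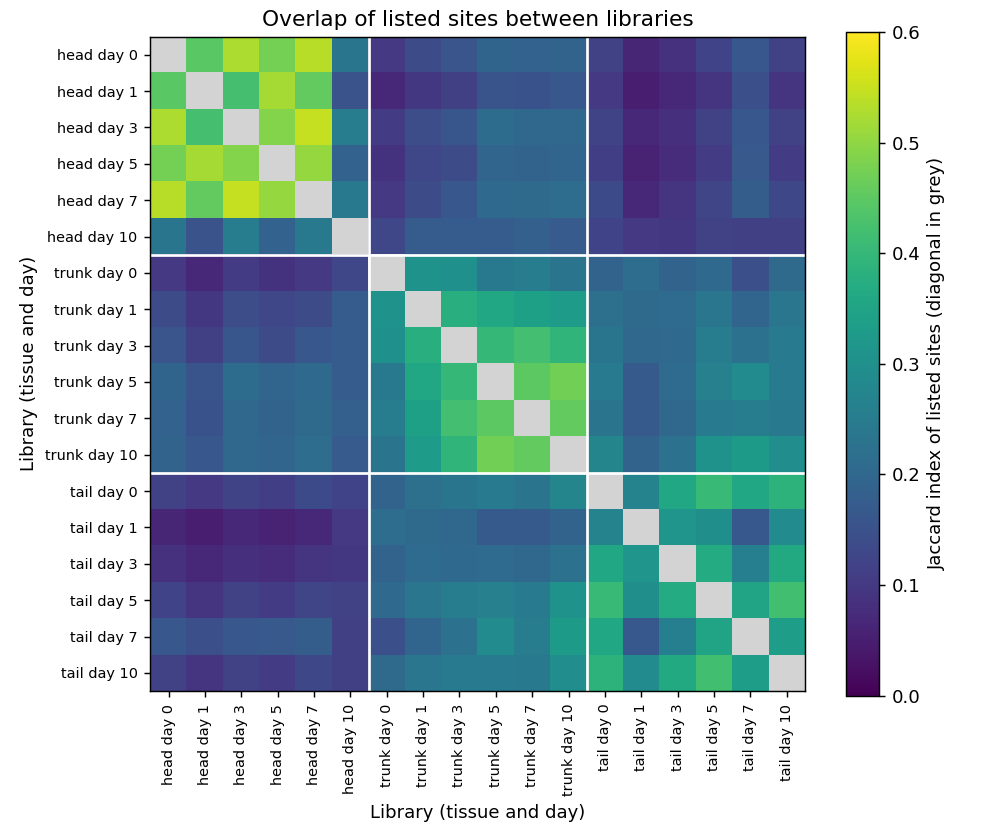
Jaccard index of listed sites for each pair of the 18 libraries, ordered by tissue and day on both axes, with white lines between tissues and the diagonal in grey. The blocks of 1 tissue average 0.399 in head, 0.355 in trunk and 0.329 in tail, and the block of head and tail averages 0.108.

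Head held the most sites seen in no other tissue. Head alone listed 2247 sites, tail alone 945 and trunk alone 311, while 890 sites were listed in all 3 tissues and 655 in trunk and tail without head. Of the 1404 sites listed on at least 4 days in head, 624 (44.4%) were in no trunk or tail library. That share was 24.2% where the control had at least 11 uncut reads and 85.0% where it had fewer. The same held for 99 of 651 recurrent tail sites (15.2%) and 17 of 618 recurrent trunk sites (2.75%). The control had a median of 12 reads at the 624 head sites and 34 at the 99 tail sites.

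At single sites, the differences between head and trunk that passed the test were all lower in head. Of 278 sites tested on 208 contigs, 16 on 13 contigs had a lower level in head and 0 a higher one (limma, adjusted p under 0.05; 51 and 2 at an unadjusted p under 0.05; 25 and 2 with the quasi-binomial model, which called 12 of the 16). The median difference of the 16 was -0.331, and 3 of them had a median under 10 reads in trunk. At position 3263 of TRINITY_DN678_c0_g2_i4, on the minus strand of a contig of 5705 bases, the level was 0.162 ± 0.0246 (SD, n = 5 days) in head and 0.797 ± 0.0119 (n = 6) in trunk, with median coverage of 9550 and 17965.5 reads (fitted difference -0.638, SE 0.0123, limma adjusted p = 0.000111). Position 1061 of TRINITY_DN13046_c0_g1_i1 had 0.144 ± 0.0417 (n = 4) in head and 0.667 ± 0.0813 (n = 5) in trunk, the latter on a median of 3 reads (difference -0.549, SE 0.0236, limma adjusted p = 0.0246). It did not pass with logit levels (adjusted p = 0.0573) or the quasi-binomial model (adjusted p = 0.244). In the other direction, 1 tested site was higher in head on every shared day, position 554 of TRINITY_DN155747_c0_g1_i1, by 0.0150 (SE 0.0047, limma adjusted p = 0.194; 0.0217 with the quasi-binomial model and 0.00978 with centring). At 122 of the 278 sites all levels were identical, mostly with no cut read. Centring each library on its sites common to all 18 shifted every site, and 135 then passed as higher in head and 20 as lower. The 135 exceed the 122 sites with identical levels, so some sites with differing levels also passed as higher only when centred. These counts do not show that any of the 16 changed direction. Without day 0, 1, 3, 5 or 7 the 16 sites became 7, 10, 9, 7 and 9, and without day 10 they became 26.

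Head against tail gave the same direction, but it used the same 6 head libraries, so it is not an independent result. Of 176 sites tested on 119 contigs, 19 on 16 contigs were lower in head and 0 higher (limma; 40 and 1 at an unadjusted p under 0.05; 27 and 1 with the quasi-binomial model, which called 13 of the 19), with a median difference of -0.266. Of the 19, 10 had a median under 10 reads in head or tail, and 9 could be tested with at least 10 reads in a library, where all 9 were among 14 calls. Some of the 19 had a tail median of 1 read. A library with 1 read at a site lists it only when that read is uncut, which fixes the level at its highest. On such days the other tissue could not come out higher, in this or the other pairs. Position 1951 of TRINITY_DN1290_c0_g1_i7, a contig of 3433 bases, had a level of 0.204 ± 0.0746 (n = 6) in head and 0.851 ± 0.0217 (n = 6) in tail on a median of 994 and 365.5 reads (difference -0.646, SE 0.0277, limma adjusted p = 0.000162). Position 3263 of TRINITY_DN678_c0_g2_i4 reached 0.776 ± 0.0233 (n = 6) in tail, a fitted difference from head of -0.609 (SE 0.0172, limma adjusted p = 0.000162). No tested site was higher in head on every shared day. Centring gave 107 sites higher in head and 24 lower, while 68 sites had identical levels in all libraries. Without day 0 the 19 sites became 12, and without day 10 they became 30.

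Trunk and tail differed at 10 of 270 tested sites, 9 higher in tail and 1 higher in trunk (limma; 38 and 2 at an unadjusted p under 0.05; 33 and 5 with the quasi-binomial model, which called all 10). Position 613 of TRINITY_DN6740_c0_g1_i1, a contig of 2407 bases, had 0.233 ± 0.0589 (n = 6) in trunk and 0.879 ± 0.0425 (n = 6) in tail, on a median of 60.5 and 26 reads (difference -0.646, SE 0.0291, limma adjusted p = 0.0006). Position 521 of TRINITY_DN11867_c10_g1_i1 was at 0.971 on 6 of 6 tail days and at 0.223 ± 0.177 (n = 4) in trunk, and the difference of -0.748 (SE 0.0854) did not pass (limma adjusted p = 0.0528). It passed in 7 of 8 alternatives that kept all days, with adjusted p from 0.000143 to 0.0491, and not with sites of at least 3 days (adjusted p = 0.103). The site higher in trunk was position 360 of TRINITY_DN19986_c0_g1_i8, at 0.260 ± 0.0033 (n = 6) against 0.190 ± 0.0254 (n = 6) on a median of 6345 and 1086 reads (difference 0.0700, SE 0.0107, limma adjusted p = 0.0362). Its adjusted p lay between 0.0556 and 0.1001 without day 0, 1, 3, 7 or 10. The 9 sites higher in tail became 4, 5, 4 and 5 without day 0, 3, 5 or 7.

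**Figure D3:**
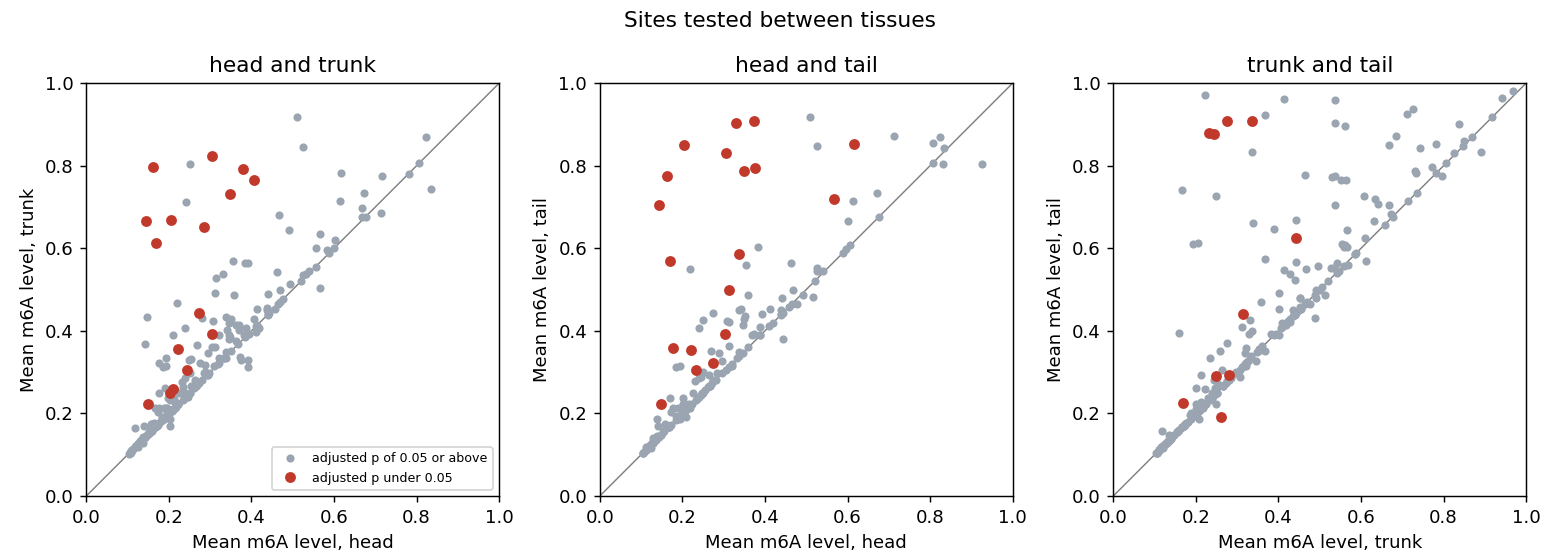
Mean m6A level (a fraction) of each tested site in the 2 tissues of a comparison, with the line of equal levels, for head and trunk (278 sites), head and tail (176) and trunk and tail (270). Red points passed an adjusted p under 0.05, and with 1 exception, a trunk site at 0.260 against 0.190, they lie on the side of the tissue nearer the tail when libraries are not centred.

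A single contig, TRINITY_DN678_c0_g2_i4, dominated the reads in trunk and led in most other libraries. In head on days 7 and 10 and in tail on day 3, TRINITY_DN155747_c0_g1_i1 led instead, with 34.4%, 39.5% and 33.6%. TRINITY_DN678_c0_g2_i4 carried 23 sites, the most of any contig, 22 of them on the minus strand, and took 88.1% ± 1.49 (SD, n = 6) of the reads at listed sites in trunk, 59.9% ± 18.1 in tail and 34.1% ± 12.4 in head. Of the reads at its listed sites 79.9% were uncut in head, 97.2% in trunk and 99.3% in tail, over 18 sites in head and 23 in each of the others. The difference was not even along the contig, as 3 positions chosen after their values were seen show. At position 448 the uncut share was 0.427 ± 0.0977 (n = 5) in head, 0.947 ± 0.0165 (n = 6) in trunk and 0.954 ± 0.0120 (n = 6) in tail, while at position 2616 it was 1 in all 3 tissues against 0.194 in the control. Position 3538 was cut in part in each tissue, with uncut shares of 0.593 ± 0.0895 in head, 0.661 ± 0.126 in trunk and 0.746 ± 0.0747 in tail. The contig with the next most sites, TRINITY_DN42680_c3_g1_i2, had 21, of which 19 were listed in tail, 12 in head and 10 in trunk.

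**Figure D4:**
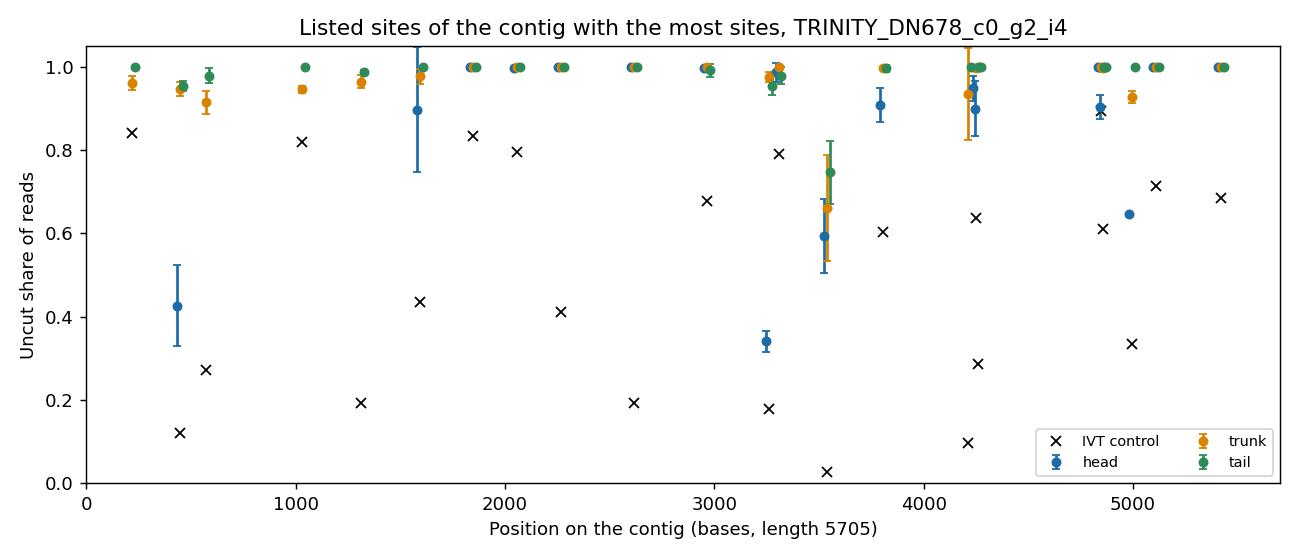
Mean uncut share of reads ± SD over days at the 23 listed sites of the 5705-base contig TRINITY_DN678_c0_g2_i4 in head, trunk and tail, with crosses for the single IVT control, plotted against position in bases (a site listed on 1 day has no SD, and tissues are set slightly apart). Most tissue points lie near 1, and head falls to 0.427 at position 448 and 0.341 at position 3263.

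Among the 39 sites in all 18 libraries, the highest mean level was at position 314 of TRINITY_DN2841_c0_g1_i3, at 0.854 ± 0.0323 (SD, n = 18) against a control uncut share of 0.13 (41 of 315 reads, 95% Wilson interval 0.0974 to 0.172). Its level was 0.823 in head, 0.869 in trunk and 0.870 in tail, where no read was cut and the control share set the value. Head was lower by less than the test could call (limma adjusted p = 0.255 against trunk and 0.167 against tail). The next was position 820 of TRINITY_DN16393_c0_g1_i2 at 0.740 ± 0.187, with 0.526 in head against 0.846 in trunk and 0.847 in tail. Its lowest coverage in any library was 5 reads.

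No difference of the median level with regeneration day passed a test, in a design that could miss it. Since 81.8% of rows had no cut read, the median mostly reflected the control. In simulated data without added spread between libraries, the site test of day 0 recovered 14.7% of 34 shifts of 0.2 and 66.7% of 12 shifts of 0.4. At sites with at least 10 reads these shares were 35.7% and 75%. The median level at day 0 exceeded that of the later days by 0.00297 (exact permutation p = 0.63), a direction that turned in 4 of 6 alternatives that kept all days, to as low as -0.00458 with sites in every library. Neither Pearson's r nor Spearman's rho with day passed the test in any tissue (6 relations). Pearson's r was -0.515 in head, 0.13 in trunk and 0.292 in tail (exact p = 0.317, 0.812 and 0.589; adjusted p = 1 for each), and rho was -0.463, 0.0857 and -0.0286 (exact p = 0.433, 0.919 and 1). Without the 2 days farthest from the median day r was -0.447, 0.678 and -0.872 over 4 days. Of 411 sites tested between day 0 and later days, 0 were higher and 1 lower at day 0 (limma; 5 and 15 at an unadjusted p under 0.05; 0 and 0 with the quasi-binomial model). The counts depended on the sites admitted, and more sites passed in both directions when sites at day 0 in any tissue were tested. The 1 site, position 433 of TRINITY_DN11186_c0_g1_i5, had a difference of -0.142 set by 2 head libraries alone, since its other levels were identical, and its residual spread was 0. It was not called without the tissue block (adjusted p = 1). Position 558 of TRINITY_DN352_c0_g1_i1 had the largest drop at day 0 of the same sign in each tissue with a value (-0.253, SE 0.216, limma adjusted p = 1). Position 623 of TRINITY_DN17348_c0_g1_i3 had the largest excess (0.346, SE 0.106, limma adjusted p = 0.749).

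Read counts of single libraries differed from day 0 at few sites, and most often in trunk. Fisher's exact test called 57 of 1568 site and day pairs in trunk (3.64%), 48 of 5647 in head (0.85%) and 14 of 2983 in tail (0.469%). The trunk calls fell on 20 of 400 tested sites, on 7 contigs, with 36 pairs higher and 21 lower on the later day. Of the 20, 12 were called on 3 or more days, and the median called difference in trunk was 0.0614 to 0.0722 by day. The percentage called also depends on the reads at the sites tested, so it does not rank the tissues by change. In head 29 were higher and 19 lower, and in tail 8 and 6. With at least 50 reads in both libraries, more tail pairs were called higher. The day 0 library is the same in all 5 pairs of a tissue, so repeated calls at a site are not independent. In trunk 3 sites were called on 5 of 5 days, and they are named here after their values were seen. Position 1951 of TRINITY_DN1290_c0_g1_i7 was higher than at day 0 by 0.278 on average, position 3538 of TRINITY_DN678_c0_g2_i4 was higher by 0.216, and position 180 of TRINITY_DN19986_c0_g1_i8 was lower (difference -0.107). In head, position 339 of TRINITY_DN155747_c0_g1_i1 was higher on 3 days and lower on 2, and position 1596 of TRINITY_DN678_c0_g2_i4 higher on 4 and lower on 1. Trunk day 0 had a median of 2 to 3 reads at the shared sites, and differences of at least 0.2 were called at 13 pairs higher and 1 lower in trunk, 2 and 3 in head, and 0 in tail.

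Against the unmodified control, the library exceeded the control at 100% of listed sites, as the lists hold only levels of at least 0.1. The median excess was the median level given for each tissue, and the median ratio of library to control share was 1.31 ± 0.0236 (SD, n = 6) in head, 1.40 ± 0.0235 in trunk and 1.44 ± 0.0138 in tail. The control was a single library of intact animals, so its own spread between libraries did not enter any comparison.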

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

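The tests in this part address patterns that had already been seen. For those by thinning reads and by control reads, the bounds were set before these tests were run. The other tests were chosen after the results were seen, and a later addition is named where it is used. Among 24 groups of 6 libraries examined for a library far from the others, 4 held one, and chance gives about 5% of groups.

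Head day 10 stood apart on 3 measures. Its log2 number of listed sites was 9.30, against 10.73 for the next lowest head library and a gap of 0.671 of the range. Its share of fully uncut sites was 88.9% (Wilson interval 86.2 to 91.1), against at most 75.6% on the other head days. Its log2 median reads at the common sites was 4.0, against 7.83 for the next. Without day 10, head minus trunk in log2 sites was 1.31, with head higher on each day left (adjusted exact p = 0.188). An exact test over 5 days cannot give a p under 0.0625 before adjustment. Tail day 7 had the lowest share of fully uncut tail sites, 92.2%, against 93.7% for the next, and the most tail sites, 2375.

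The number of listed sites differed several-fold within a tissue, and sequencing depth is a candidate explanation. The lowest of the 3 correlations between log2 sites and log2 reads at the common sites was 0.9718. When reads were thinned at random to the shallowest library of each tissue, the range of log2 site numbers fell to 32.4% of its size. The trunk rise with day did not remain, as its slope after thinning was -16.3% of the slope before (r = -0.412, exact p = 0.393). The thinned lists ran from 345.4 to 468 sites in trunk, and from 409.1 to 631 in head and 447 to 836.7 in tail, so depth may not account for all of the spread. Thinning could only take sites off a list, whereas a truly shallow library may also list other sites by chance on 1 read. The shallowest trunk library, day 0, was left whole, which lowers the slope by construction. A change with day on top of depth was thus not excluded in any tissue.

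The 624 recurrent sites found in head only may come partly from the listing rule: of the 467 recurrent head sites with fewer than 11 uncut control reads, 85.0% were in no trunk or tail list, against 24.2% (227) of the 937 sites where a single library read sufficed, so the rule could cover part of the pattern. Thinning head reads to 37.5%, the ratio of reads at recurrent trunk and head sites, left 82.2% of the 624 sites in at least 1 head list, above the 80% set beforehand as arguing against depth. That bound was wrong because recurrent sites overstate trunk depth: at 22.1%, the ratio over all listed sites, which was added after the first value was seen, 59.3% stayed. At the 227 sites, 99.3% and 95.8% stayed at these ratios, the latter also added later. This cannot decide on depth, because 1 uncut read in any head library sufficed there and both ratios come from listed sites. For all 624 sites depth and expression in head alone cannot be told apart, since the depth of trunk and tail at unlisted sites is unknown. A biological difference between body regions stays open and untested.

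Levels were lower in head than in trunk and tail, and neither different sets of listed sites nor few reads account for it alone, since the difference nearest 0 was still -0.0439 at sites listed in every library of both tissues (6 of 6 days) and -0.1269 with at least 50 reads (adjusted exact p = 0.0469). One form of a difference in MazF digestion, a change of the cut share by 1 factor at all sites, was tested. The mean-square ratio of the log2 ratio of cut shares, between sites over days within sites, was at least 18.93 where such a factor gives about 1. Permuting sites within days gave at most 3.505 against trunk (20 sites) and 5.70 against tail (10 sites; permutation p = 0.0001 for both, the smallest possible), a test added last because the plain variances differed by only 3.51 and 3.63 times, under the bound of 4 set for a variance ratio; sites with few expected cut reads were left out after a first look showed an effect of depth. The test covers only such a single factor. Sites were cut to different degrees in the control and needed a level of 0.1 to be listed, so an evenly weaker digestion could also give unequal ratios. Any other difference in digestion, a difference in preparation between tissues and a biological difference stay open, as the labels give no batch. Between trunk and tail, few reads could not be ruled out, since with at least 50 reads the difference was -0.0156.

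Other splits of the libraries were compared with the real ones. For head against trunk, 1 of 100 splits into 6 and 6 libraries, the real one, called as many as 16 sites, and the highest other called 9. Head against tail gave 19 sites against 7 at most in another split (1 of 100), and trunk against tail 10 against 8 (1 of 100). These splits were a sample of those possible and mixed tissues, which can lower their calls. With tissue labels swapped within days, only the real one of 32 labellings called as many sites in each pair, the smallest share these swaps can give. Chance is thus unlikely for these 3 but not excluded. For day 0, 71 of 100 splits into 3 and 15 called at least the 1 real site, and the highest other called 34, which points to structure among the libraries, as these splits mix tissues. When the day 0 label was moved within each tissue, a test added last, 51 of 100 placements called at least 1 site and the highest other called 9, so chance cannot be excluded there.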

How the results depend on the processing

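The tissue overlap stayed past the threshold under every alternative run (permutation p = 0.00018 or, over 5 days, 0.00065). Alternatives on control reads, 10 reads, weights, uncorrected shares and identical sites were chosen after seeing the data. Causes were not tested except where stated. Thresholds on an adjusted p in the tables, levels corrected for the control (the levels already are) and gene lists were not run, and depth limits values under 20 reads.

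Level differences without 1 day ran from -0.0497 to -0.0410 for head minus trunk, -0.0880 to -0.0792 for head minus tail and -0.0414 to -0.0365 for trunk minus tail; 5 days cannot give an exact p under 0.0625. Trunk minus tail was -0.0560 (exact p = 0.0625) at 20 reads and -0.0156 at 50, and head minus trunk -0.00542 in uncorrected shares. Day 0 against later days turned to -0.00222 with sites in 9 libraries, -0.00458 with sites in every library, -0.00412 at 50 reads and -0.000963 uncorrected. Trunk minus tail in site numbers turned to 0.18 (contigs), 0.50 (20 reads) and 0.65 (50 reads), and ran from -0.29 to 0.10 without 1 day.

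No trend with day passed under any alternative. Head r and rho turned to 0.579 and 0.6 (sites in 9 libraries), 0.266 and 0.265 (every library), 0.558 and 0.371 (20 reads), 0.704 and 0.6 (50 reads), 0.611 and 0.257 (uncorrected). Trunk turned to -0.431 and -0.169 (9 libraries), -0.423 and -0.429 (20 reads), -0.219 and -0.143 (50 reads). Tail r turned to -0.579 (9 libraries), -0.00222 (every library) and -0.387 (uncorrected), and tail rho to 0.0857 (mean), 0.435 (20 reads) and 0.174 (50 reads). Without 1 day, trunk r ran from -0.360 to 0.753 and rho from -0.1 to 0.9, tail r from -0.889 to 0.497 and rho from -0.8 to 0.2. The same-day overlap ran from -0.00178 to 0.00384.

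Calls lower and higher in head against trunk, 16 and 0, became 20 and 135 (centred), 40 and 1 (no day block), 25 and 2 (quasi-binomial), 25 and 0 (10 reads), 30 and 0 (identical sites left out), and from 7 to 26 and 0 to 1 without 1 day. Against tail, 19 and 0 became 24 and 107 (centred), 32 and 0 (no block), 27 and 1 (quasi-binomial), 31 and 0 (identical left out), and 12 to 30 without 1 day. Trunk against tail, 9 and 1, became 7 and 0 (3 days), 14 and 1 (centred), 23 and 1 (no block), 33 and 5 (quasi-binomial), 18 and 1 (identical left out), and 4 to 10 and 0 to 1 without 1 day. Centring moves sites with identical levels by construction, but those were 122 against trunk and 68 against tail, fewer than the calls higher in head. Some sites with differing levels thus also passed as higher in head only when centred. These counts do not show that a site called lower without centring changed direction. The site lower at day 0 gave 0 calls with sites in every library, centred, without block, quasi-binomial and at 10 reads, 3 weighted, 0 to 1 without 1 day, and 21 lower and 8 higher with sites at day 0 in any tissue. With sites in every library, at 10 reads or without 1 day that site was not tested.

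Fisher calls at 50 reads came to 15 higher in tail against 8. With a difference of at least 0.2 there were 2 higher and 3 lower in head, 13 and 1 in trunk, 0 and 0 in tail. As a ratio, the excess over the control was 1.31, 1.40 and 1.44 in head, trunk and tail, on another scale by construction.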

Other observations

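The measures in this part were chosen after the data were seen. Listed sites were not spread evenly along the contigs. When positions were counted in the direction of the site's strand, 57.5% of the 5847 sites lay beyond the middle of the contig. With each contig split into 10 equal parts, the share rose from 5.83% in the first part to 13.7% in the next to last and was 6.74% in the last. Sites on both strands were found on 342 of the 649 contigs with at least 3 sites. Contig orientation was not given, so the direction of transcription is unknown.

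The share of a list found again on the next day sampled is bounded by the length of the later list. Tail kept 29.3% of its day 0 sites on day 1 and 35.1% of its day 7 sites on day 10, whereas 85.8% of the day 5 sites were listed again on day 7. Head kept 78.2% of its day 0 sites on day 1 and 26.3% of its day 7 sites on day 10. Trunk kept between 58.3% and 70.3%. Counted from the later list, 75.6% of the tail day 1 sites, 86.5% of the tail day 10 sites and 74.96% of the head day 10 sites were in the list before, against 37.3% on tail day 7.

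At shared sites with at least 10 reads in both libraries, uncut shares correlated across sites within a tissue with a mean Pearson r of 0.912 in trunk, 0.891 in head and 0.813 in tail. Between tissues the mean r was 0.605 for head and trunk, 0.409 for head and tail and 0.335 for trunk and tail. These correlations are across sites, which are not independent replicates.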
